A study of Camellia sinensis with 24 samples.

How the data were processed

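Gene expression was measured with one-colour Agilent arrays in mature leaves of the tea plant (Camellia sinensis), cultivar Longjing 43. The deposited files cover 24 arrays on 6 slides of 4 arrays each, and each array was hybridised with Cy3-labelled cRNA made from 0.2 ug of RNA, per the labels' protocols. The sample titles give 8 codes with 3 arrays each. N1 and W1 carry the treatment label control, and A1, A2, A3, A4, C1 and C2 share 1 label for cold acclimation and cold stress. The protocol names 4 stages, from suitable growth conditions through gradual cooling and a return to warmth to frost, but the labels tie no code to a stage, a time point or one of the controls. For 6 samples (3 of N1 and 3 of A4) the name of the deposited file carries another code than the sample title, and the title was used. The series design counts 8 biosamples in triplicate, and nothing says that the 3 arrays of a code came from separate plants, so p-values measure only the spread between these arrays, which may be technical.

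The scanner files hold spot intensity values. Per the file headers and the submitters' processing notes they were made with Agilent Feature Extraction 10.7.1.1, which subtracted a fitted background from each spot intensity, removed spatial and multiplicative trends and replaced signals too low to measure by surrogate values. No scaling between arrays is recorded in the headers for these deposited intensity values. The authors' table of processed values is on the log2 scale. Its columns share 1 distribution with a median of 5.03 on every array, as quantile normalization leaves it, and each column correlated with log2 of the same array's processed signal at r between 0.995 and 1.00 across probes. The authors' normalization step is not given in the sources used here. That table was not centred per probe, its direction is that of the signal, and it was used as an alternative only.

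From the scanner files, control spots and spots marked as outliers by the scanner software were left out (2 to 15 outlier spots per array), and 20 probes printed at 10 spots each were averaged. That left 43623 probes of 60 bases. The values analysed are log2 of the processed signal minus the 75th percentile of that array. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which kept 28023 probes (64.2%). A total of 43 values of single probes were missing after the outlier marks. No probe was saturated on any array. Where a probe was not well above background on 1 or more arrays of the dimmer side of a comparison, its fold is given as a lower bound: the mean of the brighter side against the mean, over the arrays of the dimmer side, of the higher of the lowest signal among probes well above background on that array and the probe's own signal. The fitted log2 fold change given beside such a bound rests in part on values near background. Where a side holds several groups, the bound is against their mean and need not hold against each of them alone.

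Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 24 arrays, with 16 residual degrees of freedom and a prior of 2.55 degrees of freedom. P-values were two-sided and adjusted with the Benjamini-Hochberg method over the probes tested. A probe was called at an adjusted p under 0.05 and at least a 2-fold difference. The comparisons were the mean of the 6 cold-treated groups against the mean of the 2 control groups, each cold-treated group against the mean of N1 and W1, W1 against N1, C2 against C1, the A groups against the C groups, and a moderated F test among A1 to A4, in which a call also needed a 2-fold range of group means. These comparisons, the rule for named probes and the alternatives, except those given below as added, were chosen before the data were examined. Random blocks were fitted with duplicateCorrelation (statmod 1.5.0). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

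The array files identify probes by custom identifiers, give no description for any of them, and no table used here pairs these identifiers with genes. The 36 gene lists fixed in advance as words in gene names therefore matched 0 probes, and tests of these lists and their alternatives were not run. A search of the probe sequences for peptide motifs was tried and dropped before any difference between groups was viewed. The rule for named genes then allowed at most 2 probes that were higher and 2 that were lower per comparison: those with the largest log2 fold changes among the called probes whose values did not overlap between the groups compared, and, for all cold-treated against control groups, among called probes whose 6 cold-treated means lay on the same side of both control means. For the F test the 4 probes with the largest range of group means are named.

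The fit was tested on simulated data made from the means and residual SDs of 27996 probes with a value on every array, with 200 probes changed by known folds. For the comparison of all cold-treated with control groups it recovered 92% of probes changed 3-fold and 98% of those changed 8-fold. For A1 against the controls these shares were 72% and 96%, for C2 against C1 74% and 98%, for the A against the C groups 92% and 98%, and for the F test 72% and 92%. Between 0 and 5 unchanged probes were called per simulation. The simulated noise was independent between probes and arrays, with no difference between slides, codes or array brightness, so these shares and counts hold for such noise only. The number of arrays, 3 per group, limits the precision of each group mean.

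Slide was examined as a batch. N1, A1, A2 and A3 lay on slides 1, 2 and 5, and W1, A4, C1 and C2 on slides 3, 4 and 6, so that no slide joins the 2 sets of groups and a comparison across them cannot be made with slide as a fixed term. For those comparisons slide was fitted as a random block. Alternatives were quantile normalization, normexp background correction (offset 50) of the mean and background signals, the array median in place of the 75th percentile, no filter and a stricter filter on dim probes, the authors' values, slide and replicate number as blocks, an intensity trend with robust estimation, a fit of only the compared groups, no minimum fold, each control alone, and leaving out each array in turn. Fits with array brightness as a covariate, without the brightest and dimmest arrays, with slide fixed within each set of groups, the matching fits without that block, and of A1 to A3 alone were added after seeing the data, as was the share of each log2 difference kept under normexp. Comparisons within single slides took the spread between arrays of the same group on the same slide, pooled over the 6 slides. That spread leaves out differences between slides and any array that is alone in its group on a slide. Comparisons among A1 to A3 were first fitted on the arrays of 1 slide alone. Those fits called no probe, and the form with the pooled spread was added after that was seen. A group with 1 array on a slide is there assumed to vary like the others. Splits of whole codes were also counted after the other results were seen.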

Results

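Leaf transcript levels were compared between 6 groups of cold-treated tea plants and 2 control groups, with 3 arrays per group. The plants were 8-year-old potted plants of Longjing 43, a cultivated tea variety, taken through 1 week of suitable growth conditions, 5 weeks of gradual cooling, 1 week of warmth and 1 day of frost. The study asked how tea leaves respond to cold acclimation, the gain of cold tolerance during slow cooling, and to sudden cold. The controls are coded N1 and W1 and the cold-treated groups A1, A2, A3, A4, C1 and C2. Which stage each code stands for is not stated in the labels. The 75th percentile of the processed signal ranged from 161 on W1 replicate 1 to 591 on A3 replicate 3, with a median of 299.5 over the 24 arrays. Between 49.7% and 68.8% of the 43623 probes were well above background on an array. Arrays of the same group correlated at r between 0.957 and 0.990 across probes, those of different groups between 0.873 and 0.990, and the median within-group SD of a probe ranged from 0.20 (C1) to 0.30 (W1) on the log2 scale. No array was a copy of another.

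The first principal component held 30.1% of the variance and ran from N1, with a mean position of -92.4 ± 17.3 (SD, n = 3), through A1 at -57.8 ± 6.6 and A2 at -41.2 ± 1.7, to C1 at 77.4 ± 4.5 and C2 at 89.3 ± 3.5. The other control, W1, lay among the cold-treated groups at 10.4 ± 16.8, between A3 at -15.7 ± 9.1 and A4 at 30.1 ± 13.8. The second held 19.8% and placed A4 at -91.0 ± 7.4, apart from C1 at 53.5 ± 11.8. The third, 14.4%, spread the arrays of a code, from -66.9 to 68.3 in W1. After the part due to replicate noise was removed, A2 and A3 were the closest groups, with a root mean square difference of 0.19 on the log2 scale over the tested probes. C1 and C2 differed by 0.47, A3 and A4 by 0.51, and A4 and N1 by 1.12, the most of the 28 pairs of groups. The controls N1 and W1 differed by 0.82, more than A1 did from either of them (0.54 from N1 and 0.57 from W1).

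**Figure D1:**
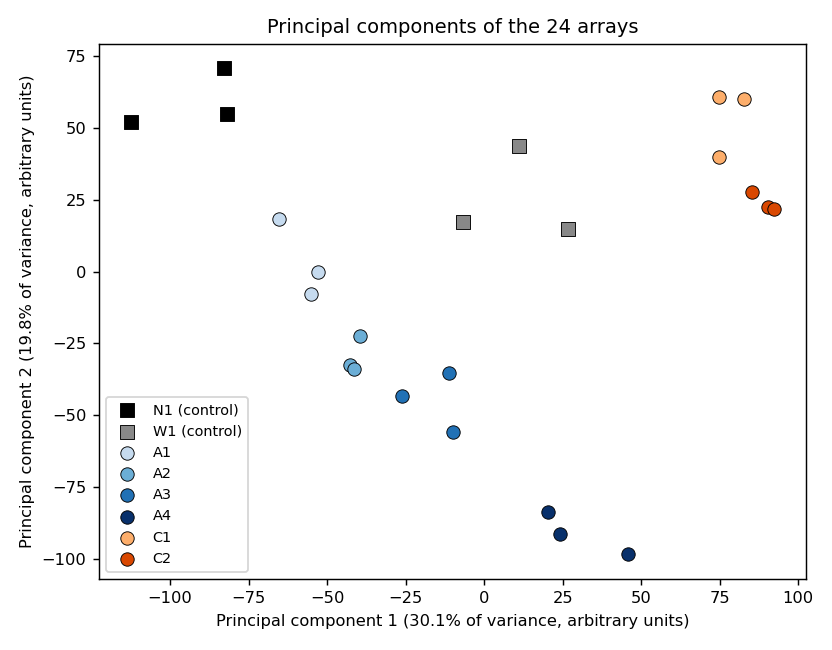
Position of each of the 24 arrays on the first and second principal components of the tested probes, in arbitrary units, with squares for the control groups N1 and W1 and circles for the cold-treated groups. Arrays of each code lie together, N1 at the left, C1 and C2 at the right and A4 at the bottom, with W1 between them.

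**Figure D2:**
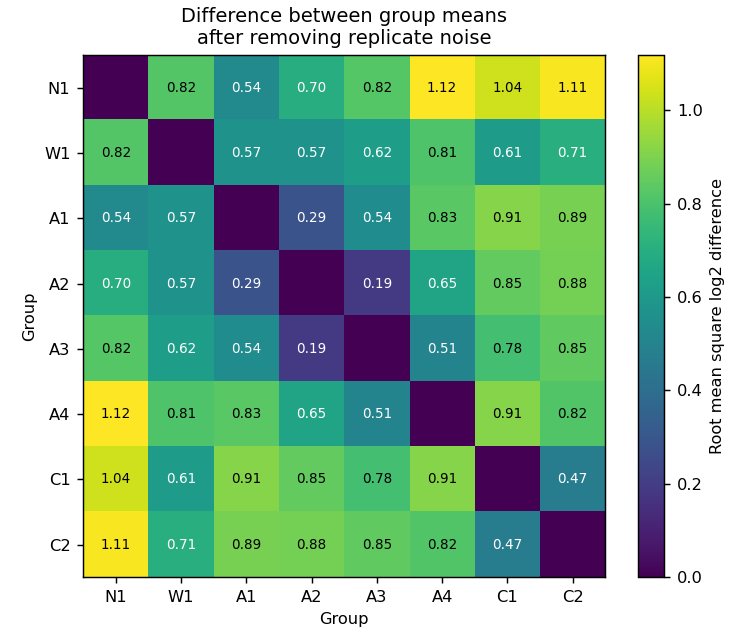
Root mean square log2 difference between the means of each pair of the 8 groups after the part due to replicate noise was removed, as colour and number. The lowest value, 0.19, is that of A2 and A3, and the highest, 1.12, that of A4 and N1.

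Across all cold-treated groups, 1750 of 28023 probes differed from the controls, 907 higher and 843 lower. The probe CUST_19276_PI429864667 was at least 13.6-fold higher in cold-treated leaves than in the mean of the controls, with a fitted log2 fold change of 4.48 (SE 0.25, limma adjusted p = 2.42e-10). It was well above background on all 18 cold-treated arrays and on 2 of 6 control arrays, and its level was highest in A4, at 2.26 ± 0.56 (log2 relative to the array's 75th percentile, SD, n = 3), against -6.07 ± 0.63 in N1 and -3.90 ± 0.40 in W1. Against W1 alone the bound does not hold. The probe CUST_13671_PI429864667 was 10.6-fold higher (log2 fold change 3.40, SE 0.17, adjusted p = 1.25e-10), with means of -0.74 ± 0.76 in N1, 0.12 ± 0.31 in W1, 0.39 ± 0.11 in A1, 4.03 ± 0.16 in A4 and 5.56 ± 0.11 in C2. The probe CUST_6991_PI429864667 was at least 6.15-fold lower (fitted log2 fold change -3.06, SE 0.24, adjusted p = 1.3e-08). It measured -0.48 ± 0.34 in N1, -0.45 ± 0.57 in W1 and -0.68 ± 0.69 in A1, near the controls, and was not well above background on any C1 or C2 array. The probe CUST_2338_PI429864667 was at least 11.2-fold lower (fitted log2 fold change -3.61, SE 0.55, adjusted p = 4.3e-05), from 4.59 ± 0.46 in N1 and 1.02 ± 1.03 in W1 to -4.41 ± 1.78 in A4. With the code as a random block only CUST_19276_PI429864667 of these 4 probes kept its call (adjusted p = 0.0188). The others had the same log2 differences as above and adjusted p of 0.0770 (CUST_13671_PI429864667), 0.110 (CUST_6991_PI429864667) and 0.239 (CUST_2338_PI429864667). In all, CUST_19276_PI429864667 kept its call in 39 of 39 alternatives, CUST_13671_PI429864667 in 39 of 40 and the 2 lower probes in 37 of 39 each. CUST_2338_PI429864667 also lost it with W1 alone as the control (adjusted p = 0.0773), at a log2 difference of -1.82, so that its bound does not hold there. The adjusted p of CUST_6991_PI429864667 was highest, 0.137, under normexp background correction, at a log2 difference of -0.76.

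Their 60-base sequences are the only identity the files give for these probes. CUST_19276_PI429864667 is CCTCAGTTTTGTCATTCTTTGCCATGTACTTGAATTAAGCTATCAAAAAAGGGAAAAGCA, and CUST_13671_PI429864667 is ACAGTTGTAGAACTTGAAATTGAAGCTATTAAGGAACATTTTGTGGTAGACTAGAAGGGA. CUST_6991_PI429864667, lower in the cold-treated groups, is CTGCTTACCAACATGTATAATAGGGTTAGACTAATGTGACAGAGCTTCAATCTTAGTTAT. CUST_2338_PI429864667, also lower, is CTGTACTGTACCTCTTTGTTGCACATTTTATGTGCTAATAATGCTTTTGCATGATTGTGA.

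In 384 of the 907 higher and 238 of the 843 lower probes, all 6 cold-treated group means lay beyond both control means. These were 35.5% of the 1750 calls. Among the calls of the other splits of the 8 codes into sides of 6 and 2, fitted in the same way, that share ranged from 4.36% to 70.6%, with a median of 19.2%. Of all 28 such splits, 6 called at least 1750 probes, the split by label included. The highest count was 3214, for C1 and C2 against the rest. The next was 2796, for N1 and A1 against the rest, where W1 is on the side of the other cold-treated codes. In that split the share with all means beyond was 61.5%. Treating the code as a random block, with 1 correlation of 0.57 within codes for all probes, left 63 probes, 53 higher and 10 lower. That fit takes its degrees of freedom from the arrays rather than the codes, so its p-values may be too small. With N1 alone as the control 4022 probes were called, and of the 1586 called with W1 alone 697 were among the 1750. Within the slides that held both labels (1, 3 and 6), 2104 probes were called, of which 1105 were among the 1750. The cold-treated arrays on them are 1 of A1, 3 of A4 and 2 of C2, and none of A2, A3 or C1.

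**Figure D3:**
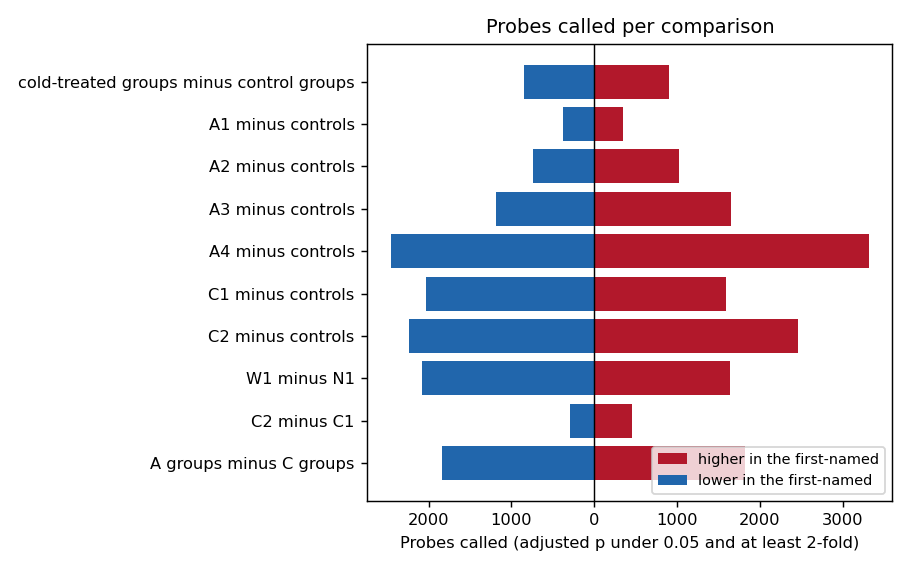
Number of probes called per comparison at an adjusted p under 0.05 and at least a 2-fold difference, higher in the first-named groups to the right and lower to the left. A4 against the controls has the longest bars, 3314 higher and 2454 lower, and A1 against the controls the shortest of the comparisons with the controls, 345 higher and 379 lower.

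**Figure D4:**
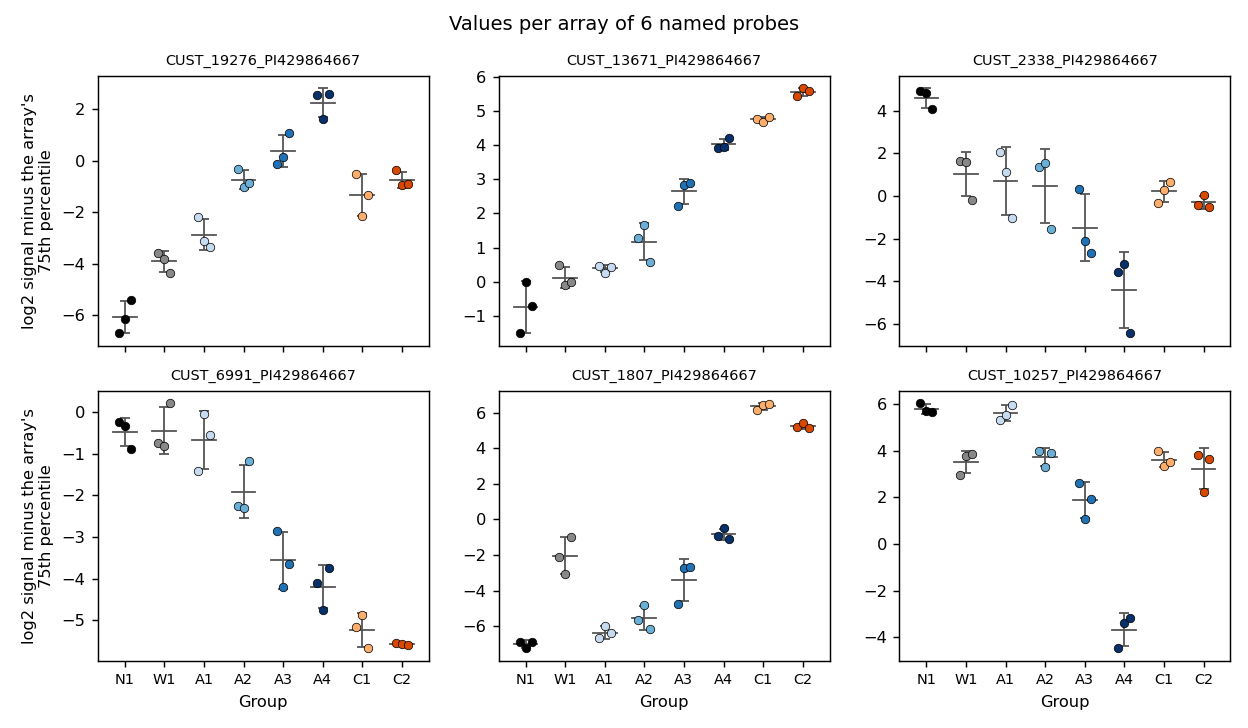
Values of 6 named probes on each array by group, as log2 signal minus the array's 75th percentile. Points are arrays, horizontal lines are group means and bars are SDs (n = 3). CUST_19276_PI429864667 rises to 2.26 in A4, and CUST_1807_PI429864667 reaches 6.35 in C1.

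The control groups themselves differed. W1 and N1 differed at 3718 probes, of which 1641 were higher and 2077 lower in W1. CUST_31088_PI429864667 was at least 181-fold lower in W1 (adjusted p = 2.6e-07), and CUST_16921_PI429864667 at least 322-fold lower (adjusted p = 1.2e-08). Both were well above background on all 3 N1 arrays and on no W1 array. They measured 3.39 ± 2.17 and 4.22 ± 1.54 in N1, which stood apart from every other group, not from W1 alone. The highest mean outside N1 was that of A1 for both, at -4.37 and -0.77. CUST_14488_PI429864667 was at least 51.9-fold higher in W1 (fitted log2 fold change 6.56, SE 0.45, adjusted p = 1.6e-08), where it measured 1.07 ± 0.18, and 1 N1 array was well above background. CUST_10310_PI429864667 was at least 25.7-fold higher in W1 (adjusted p = 7.0e-08). N1 and W1 share no slide, so slide and group cannot be told apart here, and with slide as a random block 3157 probes were called. Without a filter on dim probes 3074 were higher and 2137 lower in W1. Normexp background correction left 1065 calls, 355 higher and 710 lower.

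The A groups differed from the controls at a number of probes that was smallest for A1 and largest for A4. A1 differed at 724 probes (345 higher, 379 lower), A2 at 1764 (1024 and 740), A3 at 2845 (1656 and 1189) and A4 at 5768 (3314 and 2454). CUST_19276_PI429864667 was at least 11.6-fold higher in A2 (fitted log2 fold change 4.25, SE 0.37), 25.0-fold in A3 (5.36, SE 0.37) and 92.2-fold in A4 (7.24, SE 0.37), and CUST_8110_PI429864667 was at least 8.13-fold higher in A2 (3.56, SE 0.39) and 16.7-fold in A3 (4.60, SE 0.39). Their largest adjusted p in these comparisons was 4.1e-06. These bounds are against the mean of the controls. They do not hold against W1 alone for CUST_19276_PI429864667, or against N1 alone for CUST_8110_PI429864667, which measured -3.37 ± 0.55 in N1 and -0.72 ± 0.70 in A2. CUST_14488_PI429864667 was at least 58.4-fold higher in A4 than in the mean of the controls (6.30, SE 0.39, adjusted p = 3.1e-10). It measured 4.09 ± 0.16 in A4 and 1.07 ± 0.18 in W1, the control on the slides of A4, so that the bound does not hold against W1. The lower probes of A2, CUST_9183_PI429864667 and CUST_14840_PI429864667, were not well above background on any A2 array. They were at least 7.53-fold and 6.41-fold lower than in the mean of the controls (adjusted p = 7.4e-05 and 2.3e-06). Neither bound carries over to N1 alone, where these probes measured -1.97 ± 2.13 and -3.24 ± 1.41. Each probe kept its call in 23 of 25 alternatives, and the highest adjusted p were 0.306 and 0.415, under normexp background correction, at log2 differences of -0.90 and -0.54. With slide as a fixed term against N1 they were 0.233 and 0.230, at log2 differences of -4.16 and -2.84. The adjusted p of CUST_8110_PI429864667 in A2 was then 0.172, the highest of its 25 alternatives, at a log2 difference of 2.49.

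In A3, CUST_3005_PI429864667 was 26.6-fold lower than in the controls (log2 fold change -4.74, SE 0.17, adjusted p = 3.5e-12). Its mean was 5.55 ± 0.30 in N1 and 5.29 ± 0.06 in W1, and it was lower in each A group in turn, at 4.26 ± 0.21 in A1, 2.26 ± 0.24 in A2, 0.69 ± 0.48 in A3 and -1.46 ± 0.00385 in A4, while it measured 4.99 ± 0.10 in C1 and 5.10 ± 0.10 in C2. CUST_43100_PI429864667 was at least 13.1-fold lower in A3 (-4.83, SE 0.81, adjusted p = 0.00015), with 1 A3 array well above background. That bound does not carry over to W1 alone, where the probe measured -2.32 ± 0.42. The probe kept its call in 24 of 25 alternatives, with the highest adjusted p, 0.0901, for slide as a fixed term, where its log2 difference was -5.68. In A4, CUST_10257_PI429864667 was at least 324-fold lower (-8.34, SE 0.38, adjusted p = 8.6e-12) and CUST_14281_PI429864667 197-fold lower (-7.62, SE 0.39, adjusted p = 3.6e-11) than in the mean of the controls. Against W1, the control on the slides of A4, both folds were smaller and the bound does not hold. The probes measured 3.52 ± 0.49 and 3.46 ± 0.42 in W1, against -3.68 ± 0.70 and -3.02 ± 0.97 in A4.

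The probes named for A1 were less precise. CUST_2465_PI429864667 was 20.0-fold higher (log2 fold change 4.32, SE 0.70, adjusted p = 0.00069) and CUST_3479_PI429864667 was 11.6-fold higher (3.53, SE 1.00, adjusted p = 0.030), the second with a within-group SD of 2.90 in A1. CUST_3519_PI429864667 and CUST_36371_PI429864667 were 12.9-fold and 12.1-fold lower (adjusted p = 0.016 and 0.021), with SDs in N1 of 1.98 and 2.02. Among 27 alternative settings, CUST_3519_PI429864667 fell short of the threshold in 7 and CUST_36371_PI429864667 in 8. CUST_3479_PI429864667 did so in 11 of 26, and CUST_2465_PI429864667 in 2 of 27. Without A1 replicate 2 the adjusted p of CUST_3479_PI429864667 was 0.279 (log2 difference 1.86), that of CUST_3519_PI429864667 0.0614 (-3.74) and that of CUST_36371_PI429864667 0.0737 (-3.63). Without A1 replicate 3 those of the latter pair were 0.107 (-3.26) and 0.122 (-3.20), and that of CUST_3479_PI429864667 was 0.0502 (3.39) without N1 replicate 3 and 0.0637 (3.16) without W1 replicate 2. The highest adjusted p of the 4 probes over all alternatives, each with slide as a fixed term against N1, lay between 0.263 and 0.779. The log2 differences were then 3.52 for CUST_2465_PI429864667, -3.68 for CUST_3519_PI429864667, -3.67 for CUST_36371_PI429864667 and 1.71 for CUST_3479_PI429864667.

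The control and the slide changed the counts of the A groups. Against N1 alone 1515 probes were called in A1, 3238 in A2 and 4608 in A3, and against W1 alone 2048 in A1. Of A1, A2 and A3 only A1 shares a slide with N1, by 1 array, and A2 and A3 are linked to N1 only through the A1 arrays on slide 5. With slide as a fixed term in those 12 arrays 23 probes were called in A1, 53 in A2 and 1314 in A3, against 1281, 3199 and 4632 in the same arrays without it, and within slide 1 the 1 A1 array differed from the 3 N1 arrays at 393. A4 shares slides with W1: 5116 probes were called with slide as a fixed term and 5224 within slide 3 (2 arrays against 2). Slide 6 held 1 array of each, and neither added to the spread used within slides. Centring on the array median called 167 higher and 423 lower probes in A1, and normexp background correction called 41 in A1 (10 higher, 31 lower) and 445 in A2 (84 higher, 361 lower). Leaving out A1 replicate 3 left 453 calls in A1.

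The A groups also differed among themselves, at 5141 probes by the moderated F test. A1 or A4 held the highest mean for 1966 and 2330 of them, and A2 or A3 for 475 and 370. Among the 5141 probes A4 and A1 differed at least 2-fold at 4393, and A3 and A2 at 530. CUST_10257_PI429864667 and CUST_14281_PI429864667 had the largest ranges, at least 627-fold for the first and 382-fold for the second (adjusted p = 3.1e-10 and 1.0e-09). CUST_10257_PI429864667 measured 5.61 ± 0.33 in A1, 3.73 ± 0.39 in A2, 1.88 ± 0.78 in A3 and -3.68 ± 0.70 in A4, and CUST_14281_PI429864667 5.56 ± 0.31, 3.63 ± 0.37, 1.78 ± 0.77 and -3.02 ± 0.97. CUST_2122_PI429864667 was at least 117-fold lower in A4 than in A1 (adjusted p = 5.2e-10). CUST_10310_PI429864667 went the other way: not well above background on any A1 array, it was at least 30.8-fold higher in A4 (adjusted p = 1.7e-08). A4 shares no slide with the other A groups. A1 to A3 alone differed at 1217 probes, and at 206 with slide as a fixed term. Fits of the arrays of a single slide alone, with 2 residual degrees of freedom on slide 2 and 1 on slide 5, called 0 probes by limma for A2 and A3 on slide 2 (2872 at an unadjusted p under 0.05) and 0 for A1 to A3 on slide 5 (9210). With the spread pooled over all arrays, a form chosen after those counts of 0 were seen, 45 probes were called on slide 2 and 3819 on slide 5, where A2 and A3 had 1 array each.

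The C groups were each compared with the controls. C1 differed at 3626 probes (1591 higher, 2035 lower) and C2 at 4704 (2464 higher, 2240 lower). Against the mean of the controls, CUST_1807_PI429864667 was at least 853-fold higher in C1 (fitted log2 fold change 10.87, SE 0.43, adjusted p = 5.3e-12) and at least 396-fold higher in C2 (9.77, SE 0.43, adjusted p = 5.8e-12). Neither bound holds against W1 alone. The probe measured 6.35 ± 0.19 in C1 and 5.24 ± 0.14 in C2, -2.04 ± 1.05 in W1 and -7.01 ± 0.21 in N1, where no array was well above background. Its sequence is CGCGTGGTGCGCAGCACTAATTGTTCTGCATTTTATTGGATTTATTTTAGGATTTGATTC. CUST_12143_PI429864667, with the sequence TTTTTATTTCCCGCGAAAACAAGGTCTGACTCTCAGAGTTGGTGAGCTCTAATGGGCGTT, was well above background on all C1 and C2 arrays and on no control or A array, and was at least 34.3-fold higher in C1 than in the controls (adjusted p = 7.5e-12). CUST_14488_PI429864667 was at least 85.5-fold higher in C2 than in the mean of the controls (6.85, SE 0.39, adjusted p = 1.7e-10). That bound does not hold against W1, as it measured 4.64 ± 0.13 in C2 and 1.07 ± 0.18 in W1. CUST_24603_PI429864667 was 13.2-fold lower in C1 (-3.72, SE 0.26, adjusted p = 3.5e-09) and 35.5-fold lower in C2 (-5.15, SE 0.26, adjusted p = 3.3e-11). CUST_6991_PI429864667 was at least 14.6-fold lower in C1 and at least 11.6-fold lower in C2 (adjusted p = 7.7e-09 and 2.1e-09), and its highest adjusted p over 25 and 26 alternatives were 0.201 and 0.180, both under normexp background correction, where it was not called, at log2 differences of -1.10 and -1.05.

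W1 shares slide 6 with C2 and no slide with C1, which is linked to it only through the C2 array on slide 4. Against W1 alone, 2351 probes were called in C1 and 3434 in C2. With slide as a fixed term these counts were 798 and 2801, against 2188 and 3280 in the same arrays without it, and within slide 6 the 2 C2 arrays differed from the 1 W1 array at 2410. Against N1 alone 5829 probes were called in C1. The share of higher calls changed with the scaling: centring on the array median gave 2327 higher and 1350 lower probes in C1 and 2126 and 2717 in C2, and normexp background correction gave 675 and 280 in C1 and 983 and 494 in C2. Quantile normalization gave 2216 and 2652 in C2.

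C2 and C1 differed at 753 probes, 460 higher and 293 lower in C2. Normexp background correction left 27 calls, 18 higher and 9 lower. CUST_26341_PI429864667 was at least 3.74-fold higher in C2 (fitted log2 fold change 3.45, SE 0.61, adjusted p = 0.0023) and CUST_19522_PI429864667 at least 6.13-fold higher (3.09, SE 0.56, adjusted p = 0.0026), each well above background on 1 of 3 C1 arrays. CUST_4090_PI429864667 was at least 10.1-fold lower in C2 (adjusted p = 0.00019), and was well above background on all 3 C1 arrays, on 1 W1 array and on no other array. CUST_9434_PI429864667 was at least 10.9-fold lower (-3.45, SE 0.55, adjusted p = 0.0010). None of the 4 was called under normexp background correction, with adjusted p between 0.418 and 1.00, the highest of their 20 alternatives. With slide as a fixed term CUST_26341_PI429864667 and CUST_9434_PI429864667 were not called (adjusted p = 0.188 and 0.228), at log2 differences of 3.14 and -2.86. Under normexp background correction these were 0.83 and -1.88, and those of CUST_19522_PI429864667 and CUST_4090_PI429864667 were 0.98 and -1.39. The direction of the C2 calls as a whole depended on the scaling, with 372 of 850 higher after quantile normalization and 204 higher and 705 lower after centring on the array median. With slide as a fixed term 203 probes were called, and within slide 4, with 1 C2 array against 3 of C1, there were 258. Leaving out single arrays gave 364 (without C1 replicate 2), 397 (C2 replicate 3), 444 (C2 replicate 2), 469 (C1 replicate 3) and 1131 (C2 replicate 1).

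The A and C groups differed from each other at 3654 probes, 1819 higher and 1835 lower in the A groups. CUST_1807_PI429864667 was at least 501-fold lower in the A groups (fitted log2 fold change -9.83, SE 0.30, adjusted p = 1.7e-14), at -6.36 ± 0.35 in A1 and -0.84 ± 0.32 in A4. CUST_9139_PI429864667 was at least 68.5-fold lower (-7.75, SE 0.44, adjusted p = 5.4e-11), with 1 of 12 A arrays well above background. CUST_4416_PI429864667 was at least 12.2-fold higher in the A groups (4.21, SE 0.23, adjusted p = 3.6e-11), and CUST_45964_PI429864667, which was not well above background on any C array, was at least 7.61-fold higher (adjusted p = 7.5e-08). A total of 118 probes were higher in at least 1 A group and lower in at least 1 C group against the controls, with the difference between A and C called. Another 337 were lower in an A group and higher in a C group on the same terms. A1, A2 and A3 share no slide with C1 or C2, so slide and group cannot be told apart for them. Within slide 6, 1 A4 array against 2 of C2 gave 3694 calls, of which 1747 were among the 3654. Centring on the array median gave 1356 higher and 2170 lower probes, and normexp background correction 274 higher of 1182.

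A total of 9947 probes were called against the controls in at least 1 cold-treated group, and 21 were higher and 35 lower in all 6. All 4 A groups shared 115 higher and 121 lower probes. These comparisons use the same 6 control arrays, and overlaps were counted over the 27996 probes with a value on every array. A2 and A3 shared 789 higher and 492 lower probes, where independent lists of those lengths would share 60.5 and 31.4. C1 and C2 shared 1310 and 1198 (140 and 163 for independent lists), and A4 and C2 926 and 1003 (291 and 196). A1 and C1 shared 59 and 72 (19.6 and 27.5) and had 186 probes called in opposite directions. In 50 simulations of groups set at the mean of N1 and W1, with the spread between replicates only, no probe was called by limma in both. Independent lists of the simulated lengths would share 0 as well. No difference between codes or slides was simulated, so that count cannot tell whether such differences produce shared calls. The fold changes correlated across probes at r = 0.80 for A2 and A3, 0.77 for C1 and C2, 0.52 for A4 and C2 and -0.09 for A1 and C1, where the simulated median was 0.356 (range -0.245 to 0.797). Probes are not independent replicates. The covariances were 0.312, 0.549, 0.430 and -0.0349, against a simulated median of 0.0261. With N1 as the control of A2 and W1 as the control of A3 the shared probes were 516 higher and 261 lower, and 441 and 230 the other way round. With the controls split in these 2 ways r was 0.26 and 0.13 for A2 and A3, 0.41 and 0.42 for C1 and C2, 0.29 and 0.19 for A4 and C2, and -0.11 and -0.57 for A1 and C1. Over all tested probes, the median number of shared calls of the 15 pairs was 706, and 417 and 333 with the controls split in the same ways.

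The scaling moved the median log2 difference of all tested probes by over 0.1 in some comparisons. With centring on the array median in place of the 75th percentile it went from 0.109 to -0.0336 in A1, from -0.0270 to 0.182 in C1, from 0.0875 to -0.0291 in C2, from 0.0825 to -0.243 in C2 against C1 and from 0.125 to 0.00844 in the A against the C groups. With normexp it was 0.217 in A2, -0.128 in A3, 0.133 in C1, 0.210 in C2 and -0.105 in the A against the C groups. Normexp also shrank the differences of dim probes: of the 1750 calls for all cold-treated groups, those in the dimmest of 4 equal sets of probes kept a median of 26.8% of their log2 difference, and those in the brightest set 86.4%.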

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

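The tests of array brightness were chosen after their results were seen, and the splits of whole codes after the other results were seen. An outlier test of the 6 control arrays, run on 35 sets of values, marked 1: CUST_9183_PI429864667 measured -4.38 on N1 replicate 1, and the other 5 control arrays lay between -1.86 and -0.37. The gap was 0.627 of the range. Chance marks about 1 in 20 such sets.

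Cold-treated groups differed from each other in their change against the same controls. C2 and C1 differed at 753 probes, the A and C groups at 3654, and A1 to A4 among themselves at 5141, each by a test of the difference itself.

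W1 and N1, which share the control label, differed by 0.82 in root mean square log2. If array brightness were the whole cause, the calls should drop with log2 of the 75th percentile signal as a covariate, but 4578 probes were called against 3718 without it. Slide stays open. Arrays of the same group on different slides differed by up to 0.61 (W1) with a median of 0.41 over 6 groups after replicate noise was removed, and the largest of these is too close to 0.82 to exclude slide while none reaches it. The groups share no slide, so slide and any difference in the plants or the time of sampling, which was not tested, cannot be told apart.

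The profile changed step by step from N1 through A1, A2 and A3 to A4. The smallest step was that from A2 to A3, at 0.19 in root mean square log2. An unplanned test of A3 minus A2 over all arrays called 235 probes. Slide as the whole cause of the A2 to A3 step was argued against by the layout. Both groups were spread over slides 2 and 5 alike, so a shift common to the arrays of a slide cancels in their difference. In the planned test, A3 minus A2 inside slide 2 correlated across probes with A4 minus N1, measured on other slides, at r = 0.450, and probes are not independent replicates. On slide 5, A3 minus A1 correlated with it at r = 0.315. Each A4 array was dimmer than each N1 array (75th percentile signal 225 to 291 against 301 to 440). On slide 2, A3 (303 and 302) was on average dimmer than A2 (298 and 438). The A3 array on slide 5 (591) was brighter than those of A1 (189 and 278). Brightness was not tested as a source of either correlation. Slide stays open for the steps from N1 to A1, A1 to A2 and A3 to A4, whose differences of 0.54, 0.29 and 0.51 lie below the largest difference between slides within a group, 0.61. That largest difference, from W1, can hold array brightness as well as slide. With slide as a fixed term against N1, 23 probes were called in A1 and 53 in A2, and A4 shares no slide with A1 to A3. Those low counts do not tell slide from lost precision. Among named probes that lost their call there, the log2 difference was -3.68 for CUST_3519_PI429864667 in A1 and -4.16 for CUST_9183_PI429864667 in A2. For CUST_3479_PI429864667 in A1 it was 1.71. Array brightness as the whole cause of the difference among A1 to A4 was argued against by the 5427 probes called with brightness as a covariate. A response that grows over the stages may add to it, which the labels do not allow to be tested.

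Arrays of the same group deviated from its mean along an axis shared by all groups, which held 35.8% of the within-group variance. Position on the axis followed array brightness, both centred within groups, at Pearson r = 0.910 (permutation p = 3.0e-05, 24 arrays) and Spearman rho = 0.908 (permutation p = 1.0e-05, the smallest that 100000 permutations within groups can give). Without the 2 arrays farthest in brightness r was 0.867. Slide accounted for 36.2% of the axis, against a median of 12.3% in 10000 permutations (p = 0.0381). Adjusted over these 2 relations, p was 6.0e-05 and 0.0381. Both explanations are consistent with the axis, and no biological explanation was tested.

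Other splits of the single arrays, fitted with 2 groups only, were counted for each comparison. They break up the arrays of a code, which may not be independent, so a low share says that the arrays differ by code, not that chance can be excluded for the codes. For the cold-treated against the control groups 1 of 100 splits, the real one with 1056 probes, reached that count (highest other 868). The shares were as low for the A against the C groups (1 of 100, 3520 probes, highest other 34), for the F test among A1 to A4 (1 of 100, 5061 probes, highest other 4049) and for A4 against the controls (1 of 84, 4429 probes, highest other 2993). For A2, A3, C1 and C2 against the controls, 3, 2, 2 and 2 of 84 splits reached the real counts of 638, 1569, 2040 and 3057. The highest others, 2119, 2470, 3500 and 3419, came from the split that sets N1 apart, which also follows slide 1. For A1, 3 of 84 splits reached the real count of 3, and the split that sets W1 apart from N1 and A1 gave 1817. The large counts of the control splits point to a structure of the samples, the difference between N1 and W1, which also widens the spread of a pooled control. For W1 against N1 (2694 probes, highest other 0 by limma) and C2 against C1 (664, highest other 0 by limma) only 10 splits exist, too few for a share under 0.05.

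Splits of whole codes do not exclude chance for the cold-treated against the control groups. Of 28 splits into 6 and 2 codes, 6 called at least the 1750 probes of the real split in the fit of group means, and the highest other, C1 and C2 against the rest, called 3214. With the code as a random block 5 of 28 called at least the 63 probes of the real split, and the highest other, again C1 and C2, called 1820. For the A against the C groups only 15 splits of whole codes exist, too few for a share under 0.05. The real one called 3654 probes and the highest other 2384, and 1 of 15, the real one, reached its count.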

How the results depend on the processing

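Of 316 counts of calls under alternatives, 245 stayed within 1.5 times the reported count. That share is not one of processing alone. It includes the fits without 1 array, which moved only A1 (1 of 9) and C2 against C1 (5 of 6). Quantile normalization and the authors' values, counted separately, are nearly the same setting, with 1696 calls each for all cold-treated groups. The fits with slide fixed against 1 control, their unblocked matches, A1 to A3 alone, the brightness fits and the pooled spread within slides 2 and 5 were chosen after seeing the data. Except for the construction of the alternative (fewer probes tested, fewer arrays, a looser threshold) and the shrinkage given for normexp, the cause was not tested. Counts are given in the order all cold-treated, A1, A2, A3, A4, C1, C2, W1 against N1, C2 against C1, A against C and, last, among A1 to A4. Normexp background correction called 417, 41, 445, 821, 2369, 955, 1477, 1065, 27, 1182 and 1714. It shrank the differences of dim probes: over the comparisons of 2 sides, called probes in the dimmest of 4 equal sets by mean signal kept a median of 5.74% to 46.3% of their log2 difference, and those in the brightest set 86.4% to 97.8%, except 50.8% in A2. Probes well above background on all arrays (19489 tested) gave 793, 414, 997, 1627, 3775, 1958, 2700, 2225, 456 and 1960, with the last count inside the range. Without a minimum fold there were 11069, 2855, 6146, 8737, 12788, 9611, 10703, 8274, 1932, 13858 and 9718.

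With N1 alone as the control 4022 probes were called for all cold-treated groups, 1515 for A1, 3238 for A2, 4608 for A3 and 5829 for C1, and with W1 alone 2048 for A1 and 2351 for C1. The code as a random block left 63. With slide fixed, against N1, the calls were 23 in A1, 53 in A2 and 1314 in A3 (1281, 3199 and 4632 without the block), and against W1 798 in C1 and 2801 in C2 (2188 in C1 without the block). Within single slides A1 gave 393, A4 3788 on slide 6, C2 2410 and C2 against C1 258. For C2 against C1 slide gave 474 as a random block, 428 with the replicate block added and 203 as a fixed term, and array brightness as a covariate gave 488. A fit of A1 and the controls alone gave 272. Among the A groups, A1 to A3 alone gave 1217, 206 with slide fixed, and the arrays of slide 2 or slide 5 alone gave 0 each by limma (2872 and 9210 at an unadjusted p under 0.05). The spread pooled over all arrays, used after those counts of 0 were seen, gave 45 on slide 2 and 3819 on slide 5. The median overlap of calls, 706, became 417 and 333 with N1 and W1 as separate controls.

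Leaving out 1 array moved 2 comparisons beyond 1.5 times: A1, from 453 (without A1 replicate 3) to 955, and C2 against C1, from 364 (without C1 replicate 2) to 1131 (without C2 replicate 1), where 5 of 6 arrays did so. Replicate numbers do not pair the arrays: the median correlation of same-numbered deviations was -0.00591, none of 28 pairs of groups had all such correlations over 0.1, and 7 of 24 arrays matched best with their own number. The replicate block gave 1750, 727, 1782, 2866, 5785, 3621, 4719, 3727, 722, 3654 and 5150 and moved no count beyond 1.5 times. Named probes kept their direction in all 1153 values under alternatives and their call in 1105, and 27 of 44 results kept it under every alternative run. Signal over background limits the low side: in 10.5% (all cold-treated) to 18.2% (W1 against N1) of calls the dimmer side was not well above background. Gene list alternatives were not run, and a fixed slide term has no estimate for comparisons that join the 2 sets of slides.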

Other observations

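The test of the order below was chosen after its result was seen. C1 and C2 shared calls that no A group had in the same direction: 740 probes were higher and 401 lower in both C groups against the controls. None of these was called in the same direction in an A group, and the difference between A and C was called. Calls in the opposite direction in an A group were not left out. CUST_9139_PI429864667, with the sequence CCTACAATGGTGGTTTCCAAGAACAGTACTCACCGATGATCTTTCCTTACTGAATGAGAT, measured 1.90 ± 0.35 in C1 and 1.73 ± 0.48 in C2 (log2 relative to the array's 75th percentile, SD, n = 3), against -1.88 ± 0.85 in W1 and -4.99 ± 1.88 in N1.

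CUST_45964_PI429864667 was well above background on all N1, A1, A2, A3 and A4 arrays and on no W1, C1 or C2 array, with means of 0.58 ± 0.57 in N1 and -1.66 ± 1.18 in A4 and of -5.48 ± 1.05 in W1. A4 lies on the slides of W1, so slide alone does not sort these values.

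Of the 5141 probes that differed among A1 to A4, 3204 (62.3%) had group means in the order of the code numbers, 1765 rising and 1439 falling from A1 to A4. The next most frequent order, A2, A1, A3, A4 or its reverse, held for 499, and each of the 12 orders would hold for 8.33% by chance. As a hypothesis, the code numbers may follow time or temperature within the gradual cooling. The order of the numbers ranked 1 among the 12 orders, by the number of called probes, on the explanation that the order of the codes carries no meaning, but with 12 orders the share cannot go below 0.0833, so that the test does not settle it. Probes are correlated, and A4 shares no slide with the others.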
